A study of Rattus norvegicus with 8 samples.

How the data were processed

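Whole mPFC of rats aged 6 months was measured on a custom rat 8x15k array of Agilent, with total RNA labelled by Cy3 in one colour. Per the labels' protocols, RNA was extracted on columns, 500 ng were converted to cDNA and labelled cRNA at 40 °C, and quality was monitored on a Bioanalyzer. Groups came from the sample titles: 4 CONTROL and 4 PNFLX arrays. The free-text descriptions of 3 CONTROL samples (2, 3 and 4) mention fluoxetine, whereas their titles, source names and the authors' sheets call them control. The titles were followed. Titles number the arrays from 1 to 4, and source names number them 1, 2, 4 and 5 (CONTROL) and 1, 2, 3 and 5 (PNFLX). Title numbers are used here. Sex and litter are not given in the sources used here.

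The deposited value table is on the log2 scale. In every one of its 15207 probes the median of the 4 CONTROL arrays is 0, so each value is a difference from that median, and the direction is sample over control. The authors' sheets of changed genes hold the same log2 values, the background-subtracted signal intensity per array (Agilent's processed signal, per the file headers) and an unadjusted p-value. For the 450 listed probes, the log2 value equals log2 of the intensity minus 1 constant per array and 1 per probe, which held to 1.2e-07. The kind of scaling behind the array constants, the software and any detection flags are not given in the sources used here. The authors' p-values equalled those of a linear model without moderation on these values (largest difference of the natural log 7.5e-07). Without detection flags dim probes were not removed, and median signals are printed beside some of the large changes and list members.

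Gene names came from the authors' sheets. Of the 450 probes, 437 matched a gene of the RefSeq table for the GRCr8 assembly by gene ID or symbol and carry its current symbol, 4 kept the authors' symbol and 9 had no symbol. Differing names include Scn2a (Scn2a1 in the sheets), Adgrl2 (Lphn2), Cdk17 (Pctk2), Srsf11 (LOC502603), Hnrnpa3 (Hnrpa3), Necab3 (Apba2bp), Dnajc21 (Gs3), Prl3d4 (Csh1l1), Atp5f1b (Atp5b), Atp5mc3 (Atp5g3) and Vcan (Cspg2). The probes outside the sheets have no name in the sources used here. Set tests (camera, fry), averages over a gene's probes and the choice of a gene's brightest probe were therefore not run, and lists are given as counts of named members.

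Each probe was fitted with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 on the deposited log2 values, PNFLX minus CONTROL, without covariates, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. No 2 arrays held identical values. Simulated arrays with the real spread per probe and array (15207 probes, 200 changed) gave recovery of 6% of probes changed by 1 (log2), 26% at 2, 48% at 4 and 78% at 6, with 8 false calls. The simulated noise was independent between probes, while the real arrays share deviations across probes, so these rates need not hold for the real data. Separation of the groups was tested by exact permutation of all 35 splits of the arrays. Fisher's exact tests were run with scipy 1.17.1 in Python 3.11.15.

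The genes to name, the lists (16 pathways, 11 cell type markers), the tests and the alternatives were chosen before the data were examined, except where stated. The naming rule took the 12 largest rises and 12 largest falls past the threshold with groups apart, filled with the smallest unadjusted p. It added up to 4 members per list, 10 genes of serotonin, stress and energy signalling where named, and the 5 largest rises and falls of the authors' tables. Cacna1c and Kcnk1, further channel members, Emcn, Ndufa7, Cox6a2 and Cox4i2 were named after their values were seen. A few genes that the rule selects are not reported here, though their probes remain in all counts of probes and list members. Alternatives were quantile normalization, equal medians, equal 75th percentiles, a filter on the 25% of probes with the lowest variance, a variance trend, no moderation, array weights, other thresholds, replicate numbers as a block and leaving out each array. Leaving out CONTROL 1 and PNFLX 2 together, taking them as a block, and the Fisher tests of lists were chosen after seeing the data. The median change over all probes was -0.07 (log2) as deposited and 0.01 with equal medians, so directions were not adjusted for a shared shift.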

Results

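The medial prefrontal cortex (mPFC) of 6-month-old rats was profiled on Agilent one-colour arrays. Pups had received fluoxetine, a selective serotonin reuptake inhibitor, at 10 mg/kg (group PNFLX) or a 5% sucrose vehicle (group CONTROL) from postnatal day 2 to 21. Each group had 4 arrays, and the value table held 15207 probes with a value on all 8 arrays. Each value is a log2 signal relative to the median of the 4 CONTROL arrays for that probe, so the table gives differences and no level. Gene names and background-subtracted signals were used for the 450 probes in the authors' deposited tables of changed genes. The labels do not state that arrays of a group came from separate animals, so p-values measure the spread between these arrays. The number of arrays limits the precision.

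The first question was which transcripts of the adult mPFC differed after postnatal fluoxetine. 9 probes rose and 9 fell in PNFLX (limma, Benjamini-Hochberg adjusted p under 0.05), and in all 18 the 4 PNFLX values lay apart from the 4 CONTROL values. Passing this threshold favours such probes, so this is no further support. Over all 15207 probes, 353 (2.32%) had their groups apart, against 2.86% if the 8 values of each probe were in random order. That 2.86% ignores deviations shared between arrays, so it is no measure of chance for these arrays. Of the 18 probes, 17 had a gene symbol. The rises were led by Ppp2r2b, a brain regulatory subunit of protein phosphatase 2A, with a change of 7.13 ± 0.53 (log2, SE, n = 4 per group, limma adjusted p = 0.00906) from a median signal of 10.8 to 2146. This is 1 probe of Ppp2r2b, and its other listed probe was at 0.68 ± 0.31 (log2, SE). The falls were led by Gnl2, a nucleolar GTPase of ribosome assembly, at -6.64 ± 0.55 (SE, n = 4 per group, limma adjusted p = 0.00906), with a median signal of 1018 in CONTROL and 10.2 in PNFLX. Signals near 10 are close to the lowest listed signals of the arrays (1.14 to 14.9), so the size of such changes depends on background. At an unadjusted p under 0.05 limma gave 191 higher and 202 lower probes, 393 in all. The threshold alone would give about 760 of 15207, a count that ignores deviations shared between arrays. Among the 20 splits of the 8 arrays that part CONTROL 1 and PNFLX 2, the real one gave the most (393). The next gave 152, and the lowest 35. The 15 splits that keep these arrays together gave 425 to 3657. The 760 is therefore no measure of chance for these arrays. These splits were compared after the data were seen, and chance is not excluded for this count.

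A further 8 named genes rose. Tm9sf2, a transmembrane protein of endosomes, rose by 6.96 ± 0.60 (log2, SE), and its median signal was 9.31 in CONTROL and 1283 in PNFLX. Bri3, brain protein I3, rose by 6.32 ± 0.31, with a median signal of 22.4 in CONTROL and 2496 in PNFLX, and had the smallest adjusted p of all probes (0.000959, limma). Lxn, the carboxypeptidase inhibitor latexin, rose by 5.97 ± 0.58, from a median signal of 23.0 to 1724. Among RNA-binding genes, the splicing factor Srsf11 rose by 4.52 ± 0.37 and Hnrnpa3 by 3.73 ± 0.39, with CONTROL medians of 69.0 and 34.5. Scn2a, a voltage-gated sodium channel of neurons, rose by 3.53 ± 0.39, from a median signal of 375 to 4763. Ndrg4 rose by 2.73 ± 0.33 and Rab11a, a GTPase of recycling endosomes, by 2.69 ± 0.30. Ppp1r12a (3.75 ± 0.51, adjusted p = 0.0701), Necab3 (3.19 ± 0.45, adjusted p = 0.0781) and Psmd2 (2.44 ± 0.33, adjusted p = 0.0701) came next and did not pass in limma. The CONTROL median signal of Ppp1r12a was 6.52.

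The other falls described here were in 5 genes. Nckipsd, an adaptor that binds NCK, fell by 6.11 on the log2 scale, with an SE of 0.53, from a median signal of 3145 to 62.2. The ETS transcription factor Etv1 changed by -5.09 ± 0.41 and Lgi1, a secreted synaptic protein, by -5.01 ± 0.49. Both were held at the lowest signal of array PNFLX 1, and their PNFLX median signals were 3.67 and 8.06. Without PNFLX 1 the changes of Etv1 and Lgi1 were -4.98 and -4.69, and both passed (adjusted p = 0.0369 and 0.0389, limma), though neither passed without CONTROL 2 (adjusted p = 0.0502 and 0.0750), CONTROL 3 or PNFLX 4. The latrophilin Adgrl2 changed by -4.25 ± 0.48 and the endocytic scaffold Itsn1 by -3.62 ± 0.40. The largest adjusted p among these 5 genes was 0.0277 (limma). Slc24a2 (-5.39 ± 0.75, adjusted p = 0.0781), Dnajc21 (-4.84 ± 0.62, adjusted p = 0.0537), Rps15a (-3.79 ± 0.60, adjusted p = 0.144) and Prl3d4 (-3.35 ± 0.50, adjusted p = 0.107), of which Slc24a2 and Prl3d4 were at the same floor (PNFLX median signals 11.3 and 3.82), came next and did not pass in limma. The other listed probe of Slc24a2 was at 1.81 ± 0.55, in the opposite direction.

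**Figure D1:**
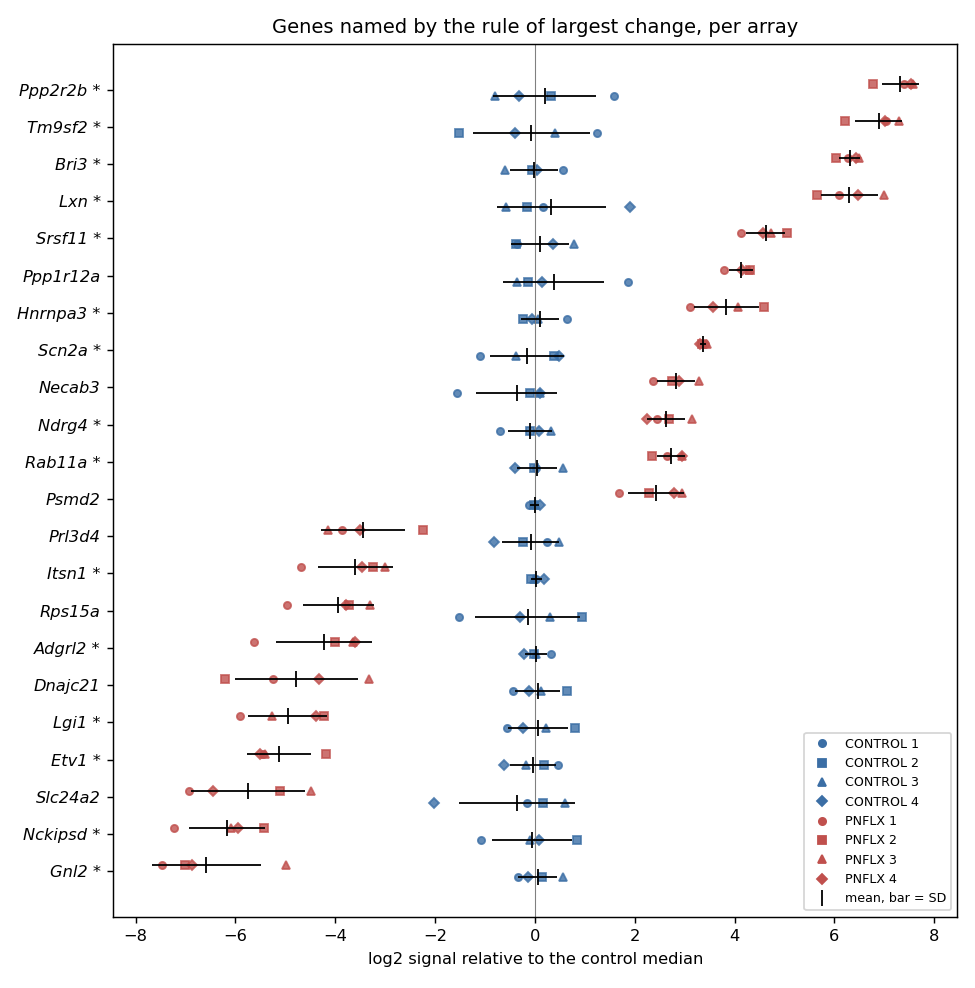
Log2 signal relative to the control median (x axis) for 22 genes of the largest-change rule (y axis), with 1 symbol per array, a vertical tick for the group mean and a bar for its SD. Asterisks mark limma adjusted p under 0.05, and the PNFLX symbols of Ppp2r2b have a mean of 7.32 with an SD of 0.37.

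These counts moved with the model and with single arrays. limma with a variance trend called 0 probes (323 at an unadjusted p under 0.05). That trend follows each probe's mean value, here a mean difference from the control median that includes the PNFLX change, so its 0 calls decide little. The array numbers as a replicate block called 0 probes, quantile normalization called 2 higher and 8 lower probes, and 75th percentiles set equal called 3 higher and 1 lower. Leaving out CONTROL 2, CONTROL 3, CONTROL 4 or PNFLX 4 left 2, 3, 4 and 2 called probes in all. Calls rose to 26 without CONTROL 1 and to 25 without PNFLX 2. Array weights, lowest for CONTROL 1 (0.131) and PNFLX 2 (0.174), gave 150 called probes, with all 18 of the main fit among them. With quantile normalization, the named genes Tm9sf2, Lxn, Srsf11, Hnrnpa3, Scn2a, Ndrg4 (2.35, adjusted p = 0.86) and Rab11a (2.34, adjusted p = 1) no longer passed, with changes at 0.702 to 0.906 of those above (log2). Control arrays lie nearer 0 by construction (SD 0.54 to 0.70 for CONTROL 2 to 4, 0.95 to 1.15 for PNFLX 1, 3 and 4). Quantile normalization removes this difference in spread too, so what these losses mean is not clear. With equal medians, Itsn1, Scn2a, Ndrg4 (2.81, adjusted p = 0.165) and Rab11a (2.77, adjusted p = 0.139) no longer passed. When single arrays were left out in turn, Bri3 passed in all 8 fits, Ppp2r2b in 6, Etv1, Tm9sf2 and Srsf11 in 5, and Gnl2 and Nckipsd in 4. Lgi1, Lxn and Hnrnpa3 passed in 3, Itsn1 in 2, and Adgrl2, Scn2a, Ndrg4 and Rab11a in 1. The changes of these 15 genes in those fits were 0.889 to 1.09 times those above (log2).

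CONTROL 1 and PNFLX 2 stood apart from the other 6 arrays. The first principal component held 62.6% of the variance after subtraction of probe means, with scores of 0.69 for CONTROL 1 and 0.51 for PNFLX 2 and scores from -0.28 to -0.10 for the others. The deviations of these 2 arrays from their group means correlated at 0.85 across probes, which are not independent replicates. Array medians were 0.79, -0.11, -0.06 and 0.06 (log2) for CONTROL 1 to 4 and 0.09, 0.59, -0.15 and -0.18 for PNFLX 1 to 4. Over all probes the correlation between arrays of one group did not exceed that between groups (mean Pearson r within minus between groups -0.02, exact permutation p = 0.457, one-sided, 35 splits, smallest possible p 0.0286). The sign of this difference turned when either array was left out (0.09 without CONTROL 1, 0.13 without PNFLX 2). Within the other 6 arrays alone, limma called 19 higher and 21 lower probes, 15 of them among the 18 called from all 8 arrays. The 2 arrays as a block gave 20 higher and 23 lower probes, with all 18 among them. PNFLX 2 minus CONTROL 1, 1 array each and without a test, was 5.19 (log2) for Ppp2r2b, 5.48 for Bri3, 4.44 for Scn2a, -6.67 for Gnl2 and -4.34 for Nckipsd. The corresponding changes in the other 6 arrays were 7.77, 6.60, 3.22, -6.63 and -6.70.

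**Figure D2:**
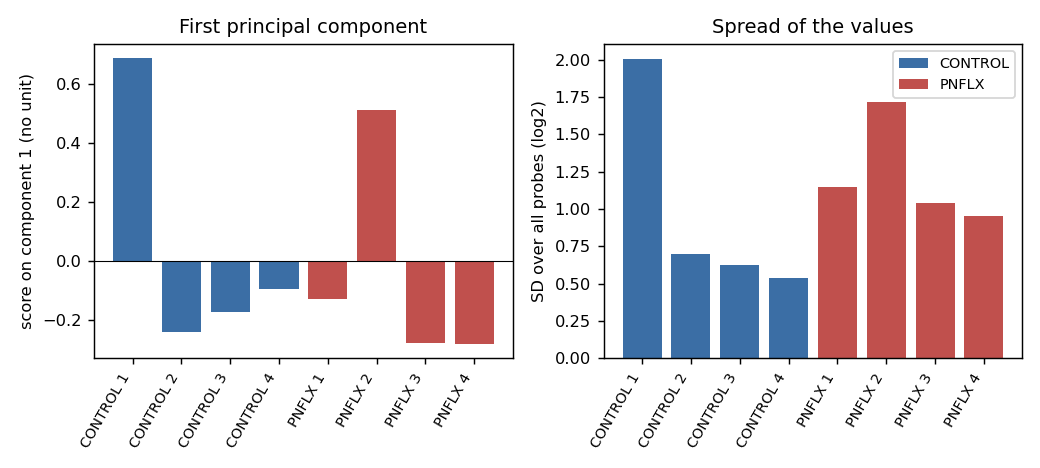
Score of each array on the first principal component (left, no unit) and SD of each array's values over all 15207 probes (right, log2), with bars coloured by group. CONTROL 1 (score 0.69, SD 2.01) and PNFLX 2 (score 0.51, SD 1.72) stand above the others, and control arrays lie nearer 0 by construction because values are relative to the control median.

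The next question was which functional groups the listed genes belong to. The lists were fixed before the data were examined, and of their members 34 genes were named in the authors' deposited tables, 17 as higher and 17 as lower. The authors chose these probes on the same arrays, so the counts are not independent evidence of direction, and set tests over all genes and counts adjusted over the list alone were not run. Only Scn2a passed in limma over all probes, so the values of other members are given without a call. In 12 of the 27 lists no member was named. Those lists were serotonin signalling, glucocorticoid and CRH signalling, synaptic vesicle and postsynaptic density, heat shock and unfolded protein response, and the markers of excitatory neurons, interneurons, astrocytes, oligodendrocytes and myelin, microglia and immune cells, erythrocytes, choroid plexus, and meninges and fibroblasts. Of the 15 lists with a named member, 14 had at most 4, too few for Fisher's exact test of higher against lower probes to reach 0.05 (smallest possible p 0.123, two-sided). The other list, ion channels, had 4 higher and 2 lower members (Fisher's exact p = 0.685, two-sided).

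The named members of the 2 mitochondrial lists were listed as higher, with the exception of Mfn1. Oxidative phosphorylation had 3 named members, all listed as higher and none past limma's threshold: Atp5mc3 (2.91 ± 0.96, log2, SE), Atp5f1b (1.59 ± 0.47) and Sdhc (1.00 ± 0.32), of ATP synthase and complex II. Without CONTROL 1 and PNFLX 2 the value for Atp5mc3 was 1.99. Respiratory chain genes outside the list were Ndufa7 (-3.57 ± 0.93) and Cox6a2 (-0.56 ± 0.24) as lower and Cox4i2 (0.51 ± 0.27) as higher, and none passed. The list of mitochondrial biogenesis, dynamics and NAD had Ppargc1a, Fis1 and Pink1 as higher and Mfn1 as lower, with none past the threshold. Ppargc1a, the coactivator PGC-1 alpha of mitochondrial biogenesis, was at 2.20 ± 0.77 (limma unadjusted p = 0.0221, adjusted p = 1), with a median signal of only 6.87 in CONTROL and 38.8 in PNFLX. For Ppargc1a the value of CONTROL 1 (2.36) lay within the PNFLX range of 1.78 to 3.64. The fission gene Fis1 was at 1.54 ± 0.36 and the mitophagy kinase Pink1 at 0.84 ± 0.27, while the fusion gene Mfn1 was at -3.81 ± 0.85, with PNFLX 1 at its lowest signal. In the mTOR and autophagy list Rps6kb1 was at 0.45 ± 0.26. Ppargc1a was the only 1 of 10 genes named in advance for the drug and tissue that the authors' tables held. The others were Slc6a4, Htr1a, Htr2a, Htr2c, Maoa, Bdnf, Nr3c1, Sirt1 and Mtor, which are not among the named probes and were not analysed here.

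Of the ion channels and transmitter receptors named, only Scn2a passed in limma. The channel list included Scn2a, which rose as given above, Scn3a (0.58 ± 0.28), Kcnj6 (0.53 ± 0.21) and Cacna1c (0.55 ± 0.29) as higher, and Kcnk1 (-0.52 ± 0.27) as lower. The receptors named from the fixed lists were listed as lower and did not pass: Gabra5 (-2.79 ± 0.94), Gabbr2 (-1.06 ± 0.39), the metabotropic glutamate receptor Grm5 (-2.10 ± 0.51) and the alpha-2C adrenoceptor Adra2c (-0.77 ± 0.28). For Gabra5 (-0.17) and Gabbr2 (-0.37) the value of PNFLX 3 lay within the CONTROL range. Receptors outside the fixed lists were listed in both directions, such as Cnr1 as higher and Gabrq as lower, chosen after their values were seen. PNFLX 1 stood at its lowest signal for Gabra5, whose PNFLX median signal was 21.2.

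The fixed-list members of this paragraph, of matrix, vessel and regulatory genes, did not pass in limma. The perineuronal net and matrix list had Vcan (-3.24 ± 0.54) and Hapln1 (-2.98 ± 0.95) as lower and Col4a1 (0.83 ± 0.34) as higher. PNFLX 1 stood at its lowest signal for Vcan, Hapln1 and Fosl2, whose PNFLX median signals were 5.59, 6.86 and 18.8. Vcan was also the single named oligodendrocyte precursor marker. The named members of the endothelial and pericyte list were Rgs5 (-3.06 ± 0.77), Anpep (-0.66 ± 0.30) and Cldn5 (-0.57 ± 0.29), all listed as lower. With quantile normalization Anpep was at -1.11 and Cldn5 at -0.92. Emcn, an endothelial gene outside that list, was listed as higher (2.08 ± 0.67, median signal 7.40 in CONTROL and 47.3 in PNFLX). The striatal marker Adcy5, from neighbouring tissue, was at 1.02 ± 0.28. Of immediate early genes, Fosl2 was at -2.69 ± 0.74 and Jund at -0.99 ± 0.40. Without CONTROL 1 and PNFLX 2 neither met the authors' criteria, with Fosl2 at -2.53 and Jund at -0.56. Chromatin modifiers were Hdac4 (0.75 ± 0.27) and Crebbp (0.55 ± 0.29) as higher and Gadd45b (-0.48 ± 0.27) as lower. Hdac4 was at 0.49 without CONTROL 1 and PNFLX 2, and Crebbp at 0.37 without PNFLX 1. Of these 3 members, 1 met the authors' criteria without CONTROL 1 and PNFLX 2. Of the ribosomal protein list, Rps26 was at 2.19 ± 0.58 and Rps15 at -1.05 ± 0.39, while Rps15a, given above, is outside that list. The growth factor Vegfa was at -0.46 ± 0.27.

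**Figure D3:**
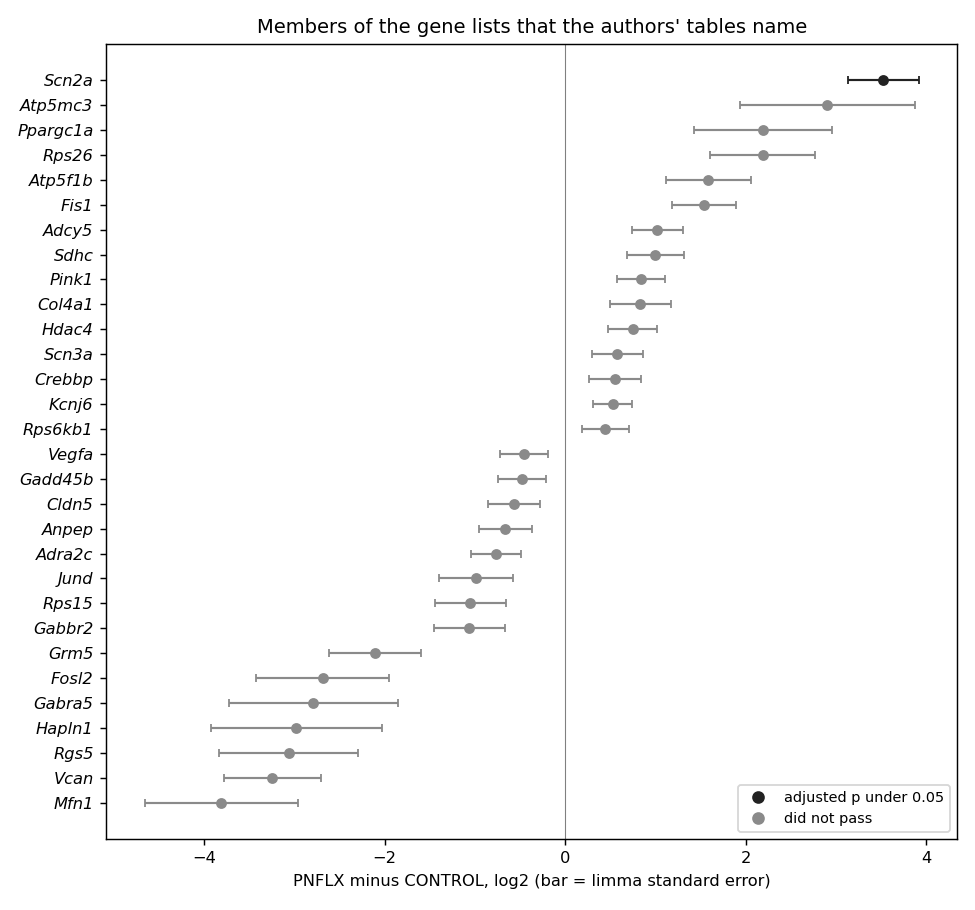
Change in PNFLX minus CONTROL (x axis, log2, bar = limma standard error) of the gene list members chosen by the naming rule (y axis), 4 arrays per group. Scn2a at 3.53 is the single member past adjusted p 0.05, and the others shown range from -3.81 (Mfn1) to 2.91 (Atp5mc3).

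The authors' deposited tables listed 225 probes as higher and 225 as lower. The same counts resulted here from a mean PNFLX value at least 0.4 (log2) from the control median together with an unadjusted p of at most 0.05 in a linear model without moderation, and each of these probes was listed. All 450 had the listed sign in the limma fit, which their selection on the same values fixes, and 18 of the 450 passed the adjusted threshold. The largest rises by the authors' deposited table were Ppp2r2b, Tm9sf2, Bri3, Lxn and Ptn, with Ptn, the growth factor pleiotrophin, at a mean of 5.21. The largest falls by the authors' deposited table were Cdk17 at -6.62, Gnl2 at -6.58, Nckipsd at -6.17, Dkk3 at -6.15 and Slc24a2 at -5.74. In limma Ptn (adjusted p = 0.127), Cdk17 (adjusted p = 0.465), Dkk3 (adjusted p = 0.188) and Slc24a2 did not pass. With quantile normalization 175 of the 450 probes still met the criteria, with array medians set equal 241, and without CONTROL 1 and PNFLX 2 316. Quantile normalization also evens out the narrower spread that control arrays have by construction, so what the 175 means is not clear.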

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

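The tests of treatment, of the large changes without 2 arrays, and those on genes with more than 1 listed probe, were chosen after the result was seen. Among 112 groups of 4 arrays examined (array medians, array SDs and the named genes), 5 had 1 array far from the other 3 by Dixon's criterion, and chance alone gives about 5.6. They were the SD of CONTROL 1 (2.01 against 0.54 to 0.70, ratio of gap to range 0.889), Etv1 in PNFLX 2 (-4.18 against -5.50 to -5.40, ratio 0.923), Gabbr2 in CONTROL 1 (-0.65 against -0.03 to 0.07, ratio 0.863), Necab3 in CONTROL 1 (-1.56 against -0.10 to 0.10, ratio 0.882) and Pink1 in PNFLX 2 (0.35 against 0.92 to 0.98, ratio 0.912). All 5 lay in CONTROL 1 or PNFLX 2. The 112 groups share the same 8 arrays, so the count against 5.6 does not decide whether these 2 arrays differ.

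CONTROL 1 and PNFLX 2, of different groups, share their deviation from the other 6 arrays. Fluoxetine is argued against by the pattern itself: CONTROL 1, by its title a vehicle array, had the highest score on the first component, and the other 3 PNFLX arrays scored from -0.28 to -0.13. That 0 of the 4 PNFLX arrays scored above CONTROL 1 follows from this pattern and adds nothing. Exchanged labels of the 2 arrays are argued against as well: of 40 probes called from the other 6 arrays, 39 (97.5%) had the same sign in PNFLX 2 minus CONTROL 1. More residual background on these 2 arrays remains a candidate explanation. Among the 450 listed probes, the deviation of each from the rest of its group fell as signal rose (Spearman rho -0.53 for CONTROL 1 and -0.513 for PNFLX 2, across probes), against -0.03 to 0.28 in the other 6 arrays, and their lowest listed signals were 14.9 and 9.09 against 1.14 to 2.97. Differences in RNA, tissue or slide were not tested.

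In 30 genes a listed probe changed by more than 16-fold. Without the arrays CONTROL 1 and PNFLX 2 these changes kept about their size. Over these 30 genes the ratio of the change without them to the change with them had a median of 1.05 (range 0.789 to 1.29). Listing required a p of at most 0.05 on all 8 arrays, which favours changes shared by the arrays, so this test cannot exclude the 2 arrays as a cause. Of 34 probes with over 16-fold change in all, 30 were listed. A change of all transcripts of the gene is argued against for Ppp2r2b and Slc24a2, whose other listed probes were at 0.68 ± 0.31 and 1.81 ± 0.55 (log2, SE), against 7.13 ± 0.53 and -5.39 ± 0.75. The smaller of these differences was 7.73 standard errors. This standard error treats the 2 probes as independent, though both were measured on the same 8 arrays, so it is only approximate. For the other 28 genes, with 1 listed probe each, a change of all transcripts and one seen by a single probe (a transcript variant, a sequence variant under the probe, or the array itself) cannot be told apart, and an effect of fluoxetine stays open for all 30.

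In PNFLX 1, 57 of the 450 listed probes were held at its lowest signal (2.97), and all 57 were listed as lower. Without PNFLX 1, 40 of the 57 (70.2%) still met the authors' criteria, as did 118 of the other 168 lower probes (70.2%, Fisher's exact p = 1, two-sided). The test leaves open whether the floor of this array may have brought some of the 57 into the list.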

How the results depend on the processing

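The 2 arrays left out or blocked together were chosen after seeing the data. Called probes numbered 9 higher and 9 lower. The value was 2 higher with quantile normalization, 3 higher and 1 lower with 75th percentiles set equal, 5 higher without the 25% of probes of lowest variance, 69 higher and 81 lower with array weights, and 0 and 0 with a variance trend (323 at an unadjusted p under 0.05). Other thresholds gave 14 higher (adjusted p 0.10), 191 higher and 202 lower (unadjusted p under 0.05), and 190 and 201 with 1.5-fold added. Without CONTROL 1 and PNFLX 2 the counts were 19 and 21, and with them as a block 20 and 23. With equal medians they were 8 and 7, of which 13 were among the 18, and without moderation 6 and 6. Leaving out 1 array gave 1 to 19 higher and 0 to 18 lower probes: 19 and 7 without CONTROL 1, 2 and 0 without CONTROL 2, 3 and 0 without CONTROL 3, 3 and 1 without CONTROL 4, 6 and 8 without PNFLX 1, 7 and 18 without PNFLX 2, 4 and 8 without PNFLX 3, and 1 and 1 without PNFLX 4. The cause was not tested.

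As a replicate block, title numbers gave 0 higher and 0 lower probes (346 at an unadjusted p under 0.05) and source name numbers 0 and 0 (206, over 6 arrays). The labels do not say whether a shared number marks a litter or day. The deviations of title pairs correlated at -0.21, -0.67, 0.44 and 0.35 for numbers 1 to 4, and not every array correlated best with its own number. Deviations sum to 0 within a group, so the shared deviation of CONTROL 1 and PNFLX 2 (0.85) also shifts the other correlations. These values therefore cannot exclude a pairing by number. The block spends degrees of freedom.

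Of gene list members, 13 higher and 12 lower ones had an unadjusted p under 0.05. Higher members numbered 3 with quantile normalization, 7 with equal medians and 7 with the title-number block, and leaving out 1 array gave 10 to 12 higher and 7 to 12 lower. Of the 450 listed probes, all had the listed sign under each alternative run, which their selection on these same arrays favours. The number past the adjusted threshold was 10 with quantile normalization, 38 without CONTROL 1 and PNFLX 2, and 2 to 26 with 1 array left out. The number meeting the authors' criteria was 175 with quantile normalization, 241 with equal medians, and 290 to 357 with 1 array left out. The separation of groups (-0.02) was -0.05 with quantile normalization, -0.07 with Spearman correlation and -0.083 to 0.13 with 1 array left out, turning positive without CONTROL 1 (0.09) and without PNFLX 2 (0.13). The cause was not tested. No named gene changed sign under any alternative run for named genes, which come from the 450 listed probes and share that selection. Of the 15 named genes past the threshold, 8 passed with quantile normalization, 11 with equal medians, 15 with array weights and 0 with a variance trend or the title-number block. A restriction to the probes of highest mean was not run, because the values keep no level. The variance trend, fitted over the same mean, carries this limit. Quantile normalization evens out a spread that is narrower in control arrays by construction. Set tests and averages per gene were not run. Changes near the lowest signals are limited by background.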

Other observations

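The tests in this part were chosen after the data were seen. Probes of olfactory receptor genes were named 3 times as higher and 13 times as lower (Fisher's exact p = 0.0191, two-sided, unadjusted). Their median signal was 10.9, and 9 of the 16 stood at the lowest signal of PNFLX 1. Over 35 gene ontology terms with at least 8 listed probes, none passed after adjustment. The smallest p was for G-protein coupled receptor signalling, with 4 higher and 16 lower probes (Fisher's exact p = 0.00422, adjusted p = 0.148), and ATP binding had 12 higher and 3 lower probes (p = 0.0294, adjusted p = 0.257). The term olfactory receptor activity had 3 higher and 11 lower probes. Terms can share probes, and the overlap with the receptor signalling term was not counted, so these are not separate results.

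Other named genes of neurons and mitochondria were chosen after their values were seen. Dcx, doublecortin of immature neurons, was at 1.68 ± 0.43 (log2, SE, limma adjusted p = 0.628), and the cannabinoid receptor Cnr1 at 0.85 ± 0.36 (adjusted p = 1). The complex I subunit gene Ndufa7 was at -3.57 ± 0.93 (adjusted p = 0.665), opposite to the named oxidative phosphorylation members. The 2 listed probes of Adnp lay at 1.62 ± 0.39 and -0.60 ± 0.27. In the other 8 genes with 2 listed probes apart from Ppp2r2b and Slc24a2, both had the same direction.

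The 18 called probes were compared with other splits of the 8 arrays. Only 1 of the 35 splits, the real one, gave as many called probes, and the highest of the others gave 1. This share is the smallest that 35 splits can give (0.0286). Only 20 of the 35 splits part CONTROL 1 and PNFLX 2 as the real one does, so chance is not excluded for this count. limma with a variance trend, title numbers as a block or source name numbers as a block called 0 probes (323, 346 and 206 at an unadjusted p under 0.05). The trend follows a mean difference and no signal level, and the blocks spend degrees of freedom. The authors' criteria, with group means compared, gave 447 probes in the real split, and 15 of the 35 splits gave as many, up to 2791 for CONTROL 1, CONTROL 4, PNFLX 1 and PNFLX 2 against the rest. Over all 35 splits chance is not excluded for the length of that list. The 14 other splits with as many probes all keep CONTROL 1 and PNFLX 2 together, as 15 of the 35 splits do, which points to a structure of these arrays. Among the 20 splits that part these 2 arrays, as the real one does, the real split gave the most (447), and the next gave 216.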
